A study of Salmonella enterica with 9 samples.

How the data were processed

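Cultures of strain 14028s were grown overnight in LB at 37 °C, washed in 10 mM MgCl2 and set to an OD600 of 1, per the labels' protocols. 2 mL of this suspension was placed in a dialysis tube inside a tube with 30 mL of medium. Minimal medium held glucose at 1.23 mM, magnesium sulfate at 2 mM and M9 salts at 20%, and soil suspensions held 33% soil by volume in MgCl2, per the labels. The growth protocol names minimal medium as the outer medium for every library, whereas the source and medium labels name the soil suspension; the latter set the groups. The time in the medium is not given in the sources used here. Ribosomal RNA was removed, the RNA was fragmented by ultrasound and libraries were made with a small RNA kit, per the labels' protocols. Each group had 3 libraries. The labels do not say whether these came from separate cultures, so the authors' p-values measure only the spread between these libraries.

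Bowtie2 (listed with version 0.6), Cufflinks 2.2.1 and Cuffdiff are named per the submitters' processing notes; their settings are not given in the sources used here. The table has the layout of a Cuffdiff test by transcription start group, per the file headers. The authors gave 1 FPKM value per group and feature, pooled over its libraries. FPKM in its plain form scales fragments by feature length and library total, and a large share of rRNA or tRNA in a library then lowers all other values. The FPKM times length summed over all features was not equal between the groups, so these values may carry another scaling. How far rRNA or tRNA lowered the other values here is therefore not known. The authors' deposited log2 fold changes use no pseudocount and are infinite where a value is 0. The test score, the p-value and the q-value of each comparison are those of the authors' deposited table. The smallest deposited p-value was 5e-05, and its q-value of 0.000271 was held by 271, 260 and 43 of the calls for DS against MM, DA against MM and DS against DA. Recomputing the Benjamini-Hochberg adjustment over the 3110 tests of all comparisons matched the deposited q-value in 100% of tests within 0.01. A feature was called where the deposited q-value was under 0.05 and the test had been run. Sequences were placed on the chromosome of strain LT2, per the sequence name in the table, although the strain was 14028s; positions are on that chromosome and counted from 1. Plasmid genes were not analysed here.

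Features were matched by name and position to the RefSeq gene table of assembly ASM694v2 for their class and length, and 4591 of 4600 matched. For 1392 features the authors' locus overlaps that of another feature, so reads may be split between them and their values are uncertain. Of the features named below these are aceK, flhD, glnA, ilvG, infA, leuA, leuB, narG, potI, STM4255, trpB, trpD, yhbO and ysdB. The 28 features whose name occurs more than once were left out of the gene lists and named genes. In lists of protein genes, features of another class were left out, since symbols such as cysT and metT denote tRNA genes in this annotation.

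The files held values per group and not per library, which the fixed design had foreseen. No test between libraries was therefore run, and the authors' calls are described. Changes were computed as log2(FPKM + 1) differences, and folds as ratios of FPKM where both values were above 0. The pseudocount understates changes of low features. For each of the 52 protein gene lists fixed before the data were examined, tested members called higher or lower were counted. A second count was adjusted over the list alone, by the Benjamini-Hochberg method on the authors' p-values. Lists with at least 5 tested members were compared with the other tested protein-coding features by two-sided Fisher's exact tests for each direction, adjusted together within a comparison. Members of an operon are not independent, so these p-values describe the lists. The list median was set among 10000 random lists matched on expression in 10 bins.

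Genes were named by a rule fixed before the data were examined. It takes the 6 largest increases and 6 largest decreases among calls of at least 2-fold with a symbol and at least 10 FPKM in the higher group. It adds, for the 8 lists with the largest share of called members (at least 5 tested and 3 called), up to 4 members in the main direction and 2 in the other. For lists without calls it allows the 2 members with the highest mean, with values only. Fewer than 8 lists met the rule in the comparison of the soil suspensions, where 6 are described.

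Alternatives covered a 2-fold minimum, a q-value under 0.01, a minimum of 10 FPKM, values above 0 in both groups, pseudocounts of 0.1 and 5, and centring on the median. Scaling to protein-coding or rRNA features and a q-value recomputed within each comparison were added after the data were examined. The list tests were tested on simulated data: in 100 tables of 983 features for the comparison of the soil suspensions, lists made to change were found in 100% and unchanged ones in 3%. The corresponding shares were 100% and 0% for DS against MM on 892 features, and 100% and 3% for DA against MM on 865 features. The simulated features were independent, the simulated lists were larger than most lists tested here, and their p was not adjusted. These shares therefore check the code and do not give the power of the list tests on these data. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.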

Results

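RNA of Salmonella enterica serovar Typhimurium strain 14028s was sequenced after incubation in 3 media, with 3 libraries per medium and 9 in all. Minimal medium (MM) held diluted M9 salts, magnesium sulfate and glucose. The other media were a suspension of a soil called DS in the labels and a suspension of the same soil after autoclaving, here DA. The cells sat in dialysis tubes placed in the medium. The authors gave 1 FPKM value per medium for each of 4600 features, each a group of transcripts with a common start on the chromosome. No value per library was used here, so no spread between libraries stands beside the values below. Whether a difference exceeded that spread rests on the authors' Cuffdiff test alone, and a feature is called where their q was under 0.05.

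Depth differed between the media. In MM, 54.7% of the features were listed at 0, against 13.7% in DS and 18.3% in DA. At least 10 FPKM was reached by 233 features in MM, 465 in DS and 482 in DA. Among features of at least 900 nt, the most common product of FPKM and length in kb was 0.27 in MM, 0.06 in DS and 0.10 in DA. The lowest steps in MM were therefore 4.5 times as coarse as in DS. Counted in these steps, the summed protein-coding signal was 30166 in MM, 302502 in DS and 210836 in DA. Folds against MM values near or below 1 FPKM rest on few steps and are uncertain. A feature listed at 0 in MM was thus not detectable at this depth, and no fold is given against it. The authors' test was run on 1014 features for DS against MM, 989 for DA against MM and 1107 between the soil suspensions. 3445 features, or 74.9%, were tested in no comparison.

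The first comparison asked how the transcriptome in untreated soil suspension differed from that in minimal medium. On the authors' scale most called protein-coding features were higher in DS, while rRNA and most tRNA features were lower. Among named features, the largest increases were in ybeC (482.7 FPKM), yodD (223.4 FPKM), rpmJ (147.4 FPKM), yjjY (114.6 FPKM), bolA (104.3 FPKM) and yoaG (89.7 FPKM), all listed at 0 in MM. rpmJ encodes a ribosomal protein and bolA a regulator of cell shape. Most of these features are short, with rpmJ at 3585886 to 3586002 and yjjY at 4856200 to 4856340. FPKM in its plain form divides by length, so few reads can give a short feature a high value. The ranking may therefore favour short features. The largest decreases were in 4 tRNA genes, ileX, selC, tyrU and cysT, and in ybfA and glgS. ybfA fell 24.9-fold, from 887.7 to 35.6 FPKM, and glgS, linked to glycogen synthesis and surface properties, fell 17.5-fold, from 728.1 to 41.6 FPKM. selC, the selenocysteine tRNA, fell 18.8-fold, and ileX went from 1360 FPKM to 0.

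By the authors' deposited table, 504 of the 1014 tested features were called, 369 higher and 135 lower in DS. The called features included 366 protein-coding features that were higher and 34 that were lower. All 21 rRNA features and 74 of the 85 tRNA features were lower, although the tRNA median was 0.09 above 0 when rRNA was taken as constant. As a share of the summed FPKM times length, tRNA made up 40.1% in MM, 51.1% in DS and 51.9% in DA, rRNA 48.4%, 35.5% and 30.0%, and protein-coding features 0.129%, 0.882% and 0.739%. MM was listed at 0 for 202 of the called features. The tested protein-coding features had a median change of 1.98 on the log2(FPKM + 1) scale, so the direction of single genes depends on the scaling. Over the 1909 protein-coding features above 0 in both media, tested or not, the median log2 ratio was 1.05. Calls were higher in 73.2% as given, in 61.5% after centring on the median of all tested features, in 57.5% after centring on that of tested protein-coding features, and in 87.5% when rRNA was taken as constant. Changes of gene groups are therefore also given relative to the tested protein-coding median. At least 10 FPKM in the higher group was reached by 304 of the calls, and 298 had values above 0 in both media.

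Of all 892 tested protein-coding features, 366 were called higher in DS, and the list counts below are to be read beside this share. Genes of protein synthesis were among those higher in DS. In the list of translation and transcription machinery, 14 of 18 tested members rose and 4 did not pass (14 rose when adjusted over the list alone), with a median 0.21 above the shift. The elongation factor gene fusA rose 20.0-fold, from 1.19 to 23.9 FPKM, and the sigma factor gene rpoD rose from 1.39 to 20.8 FPKM. infA and efp reached 10.6 and 8.34 FPKM from 0. Of 52 tested ribosomal protein features, 26 rose and 26 did not pass (30 rose when adjusted over the list alone), with a median 1.01 above the shift. Cold shock genes rose in 8 of 9 tested members (9 when adjusted over the list alone). Their median was 0.35 above the shift. The list did not hold more higher calls than other features (adjusted p = 0.106, two-sided Fisher's exact test), and did so only with q recomputed within this comparison (adjusted p = 0.0375, same test). The RNA chaperone genes cspC and cspE rose 10.6-fold and 7.91-fold, cspE to 6188 FPKM. The nuclease gene pnp rose 10.7-fold, and cspB reached 11.4 FPKM from 0.

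Glycolysis genes rose in 7 of 9 tested members (8 when adjusted over the list alone), with a median within 0.01 of the shift. The enolase gene eno rose 33.2-fold, from 1.03 to 34.1 FPKM, fba rose 19.1-fold, pykF rose 15.6-fold and gapA rose 14.9-fold. Branched-chain biosynthesis and transport rose in 9 of 12 (9 when adjusted over the list alone), with a median at -0.01 relative to the shift, among them livJ (8.25 FPKM), ilvE (4.38 FPKM), ilvG (4.17 FPKM) and ilvC (3.84 FPKM), all listed at 0 in MM. Curli and cellulose genes, for surface fibres and matrix, rose in 5 of 7 (5 when adjusted over the list alone), with a median 1.99 above the shift. csgA, the major curli subunit, rose 22.1-fold, from 2.68 to 59.1 FPKM, and yhjR reached 17.2 FPKM, csgE 5.78 FPKM and csgF 4.40 FPKM from 0. NADH dehydrogenase I genes rose in 3 of 5 (3 when adjusted over the list alone), namely nuoA, nuoB and nuoI, with a median 0.40 above the shift. Nitric oxide stress genes rose in 3 of 5 (4 when adjusted over the list alone), with yoaG, hcr (8.51 FPKM) and yeaR (7.02 FPKM) from 0 and a median 1.27 above the shift. Heat shock and chaperone genes rose in 9 of 15 (11 when adjusted over the list alone), including clpX (11.3-fold), hflB (7.82-fold), rpoH (7.74-fold) and ibpB (3.72 FPKM from 0). Their median lay below the shift, at -0.64 relative to it.

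Of the other lists, genes linked to the stationary phase regulator RpoS gave 15 higher and 2 lower among 29 tested, with a median 0.72 above the shift. Of its 9 tested members listed at 0 in MM, 8 were called. By contrast, yjbJ went from 6.33 to 222.9 FPKM and dps from 0.751 to 16.0 FPKM without a call (both q = 0.228 in the authors' deposited table). A member that did not pass against MM was therefore not always unchanged. The TCA cycle gave 3 higher among 8, with a median at -0.41 relative to the shift, and oxidative stress 2 higher and 1 lower among 8, with a median 0.27 above it. Iron uptake gave 5 higher and 3 lower among 17, with a median at -1.19 relative to the shift, and zinc and manganese uptake gave 2 lower among 5, with a median at -3.38. Nitrogen limitation gave 6 higher among 15, envelope stress 6 among 12, and anaerobic respiration and fermentation 7 among 17, with medians 0.24, 0.76 and 0.15 above the shift. For none of the 24 lists tested did an excess of calls over other tested protein-coding features pass at an adjusted p under 0.05. The smallest adjusted p was 0.106 by two-sided Fisher's exact test over 48 tests, and 6 lists had an unadjusted p under 0.05.

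The same question was asked of autoclaved soil. Against MM, the pattern in DA had much in common with that in DS, with the genes of acetate use and the phosphotransferase system among the higher ones. The largest increases were in ybeC (846.2 FPKM), yodD (820.3 FPKM), the small regulatory RNA dsrA (421.8 FPKM), rpmJ (256.2 FPKM), bolA (221.7 FPKM) and yaiA (192.0 FPKM), all listed at 0 in MM. Most of these are again short, with dsrA at 2068647 to 2068730. dsrA had q = 0.0442 in the authors' deposited table. In DS it was at 57.8 FPKM and was not tested against MM. The largest decreases were in the tRNA genes ileX, cysT, leuZ and tyrU, in ychH and in csrB. csrB, a small RNA that sequesters the regulator CsrA, fell 22.2-fold, from 10739 to 484.2 FPKM, and ychH fell 38.7-fold, from 254.4 to 6.58 FPKM. tRNA and rRNA features can share reads with near-identical copies, so their single values are uncertain.

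By the authors' deposited table, 482 of the 989 tested features were called, 364 higher and 118 lower in DA. Of 865 tested protein-coding features, 357 were called higher and 34 lower, and the list counts below are to be read beside this share. All 21 rRNA features were lower, as were 59 of 85 tRNA features, while 2 tRNA features were higher, and the tRNA median was 0.69 above 0 with rRNA as constant. MM was listed at 0 for 206 of the calls. The median of the tested protein-coding features was 2.11 on the log2(FPKM + 1) scale, and the median log2 ratio was 0.91 over the 1843 protein-coding features above 0 in both media. Calls were higher in 75.5% as given, in 65.1% after centring on all tested features, in 59.1% after centring on tested protein-coding features, and in 90.9% with rRNA as constant. At least 10 FPKM in the higher group was reached by 299 of the calls, and 270 had values above 0 in both media.

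Genes of glucose and mannose uptake rose in 4 of 5 tested members (4 when adjusted over the list alone), with a median 1.44 above the shift. ptsI rose 23.6-fold and crr 15.3-fold, while ptsH (147.0 FPKM) and ptsG (8.26 FPKM) were listed at 0 in MM. Gluconeogenesis and the glyoxylate shunt, which allow growth on acetate, rose in 6 of 9 (6 when adjusted over the list alone), with a median 1.62 above the shift. aceB, aceA and aceK reached 81.2, 56.3 and 57.4 FPKM from 0, and the acetyl-CoA synthetase gene acs rose 50.9-fold, from 0.325 to 16.5 FPKM. The acs fold rests on few of the lowest steps in MM, and its change was 3.72 on the log2(FPKM + 1) scale. Genes linked to RpoS gave 16 higher and 2 lower among 30 (18 and 2 when adjusted over the list alone), with a median 1.15 above the shift. bolA, elaB (83.4 FPKM), osmE (75.5 FPKM) and osmY (48.6 FPKM) rose from 0, while ychH and uspA fell, uspA by 3.66-fold.

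Nitrogen limitation genes rose in 4 of 6 tested members (4 when adjusted over the list alone), namely gltI (16.4-fold), potF (9.19-fold), dppA (5.14-fold) and potI (3.37 FPKM from 0). Their list median lay at -0.19 relative to the shift. The change of dppA turned to -0.42 on the log2 scale after centring on all tested features. Cold shock genes rose in 6 of 8 (7 when adjusted over the list alone), with cspC 11.1-fold, deaD 8.92-fold and cspE 5.30-fold higher and cspB at 13.3 FPKM from 0, and a median 0.04 above the shift. Translation and transcription machinery rose in 10 of 15 (11 when adjusted over the list alone), including fusA (22.3-fold) and rpoD (19.6-fold), with greA and efp at 6.83 and 6.66 FPKM from 0 and a median 0.27 above the shift. Glycolysis rose in 6 of 10 (8 when adjusted over the list alone), with eno 38.2-fold, pykF 22.7-fold, fba 19.6-fold and gapA 13.8-fold higher and a median at -0.13 relative to the shift. Heat shock and chaperone genes rose in 7 of 11 (7 when adjusted over the list alone), including clpX (14.6-fold), hflB (8.22-fold), lon (7.37-fold) and rpoH (6.09-fold). Their median lay at -0.78 relative to the shift, and lon turned to -0.14 after centring on all tested features. Relative to tested protein-coding features, deaD (-0.22), rpoH (-0.03) and potF (-0.05) also lay below 0. Ribosomal protein features rose in 23 of 52, with a median 0.93 above the shift. For none of the 18 lists tested did an excess of calls over other features pass at an adjusted p under 0.05. The smallest adjusted p was 0.590 by two-sided Fisher's exact test over 36 tests, and 0 lists had an unadjusted p under 0.05.

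The responses to the soil suspensions overlapped. Of 848 features tested against MM in both, 284 were called higher in both and 112 lower in both, and 0 were called in opposite directions. Independent lists of these sizes would share 111.9 higher and 18.8 lower features. These values ignore that direction followed RNA class on the authors' scale. All 21 rRNA features were lower in both, as were 74 tRNA features in DS and 59 in DA. Only 34 protein-coding features were lower in each. MM was listed at 0 for 202 calls in DS and 206 in DA. The excess therefore does not measure a shared response of genes. Both comparisons use the same MM libraries, so part of the excess may come from the shared controls. Its size could not be simulated without values per library.

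**Figure D1:**
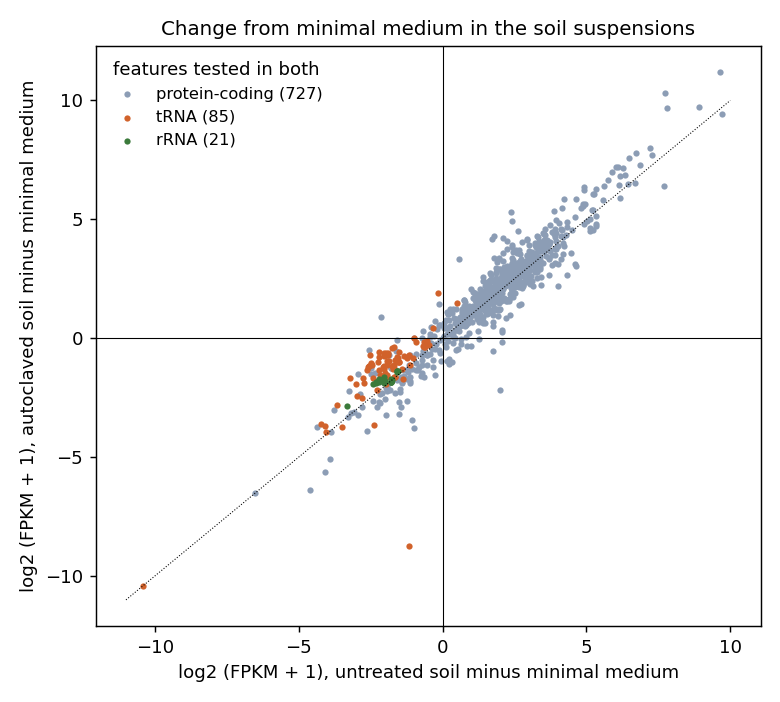
Change of the protein-coding, tRNA and rRNA features tested in both soil comparisons, as log2(FPKM + 1) in untreated soil minus minimal medium (horizontal) and in autoclaved soil minus minimal medium (vertical). Points are protein-coding (727), tRNA (85) and rRNA (21) features, the dotted line marks equal change, and the 21 rRNA features lie below 0 on both axes.

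The last comparison asked what autoclaving the soil changed, and it is also the test of the difference between the responses above. Several genes of the nitrogen limitation list, several curli genes and the nitrate reductase gene narG were higher in untreated soil. Several genes for branched-chain amino acid synthesis and the glyoxylate shunt were higher in autoclaved soil. The largest decreases in DA were in glnK, asnA, csgB, orfX, csgA and narG. The asparagine synthetase gene asnA, at position 4085321 to 4086313 of the LT2 chromosome, was at 147.8 FPKM in DS, 2.995 FPKM in DA and 1.29 FPKM in MM, a 49.3-fold difference between the soils. The nitrate reductase gene narG was at 15.5 FPKM in DS and 0.220 FPKM in DA, and its locus overlaps other features. orfX fell from 34.5 FPKM to 0. The largest increases in DA were in ilvB, ilvG, yfhP, ilvE, ilvD and ilvA. yfhP, the gene of an iron-sulfur cluster regulator, was at 39.6 FPKM in DA and 5.16 FPKM in DS, a 7.68-fold difference. For asnA, glnK, csgB, ilvB, ilvG, ilvE, ilvD, ilvA and yfhP, q was 0.000271 in the authors' deposited table, the smallest value there.

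By the authors' deposited table, 147 of the 1107 tested features were called, 94 higher and 53 lower in DA. The higher ones included 55 protein-coding and 33 tRNA features, and the lower ones included 52 protein-coding features. The median of the tested protein-coding features was 0.13 on the log2(FPKM + 1) scale, and 63.9% of the calls were higher under each scaling tried. These scalings kept the authors' calls and subtracted small shifts, so the share could hardly change. The summed protein-coding signal was 0.216 higher in DA as a log2 ratio on the authors' scale. As a share of all summed signal it was 0.882% in DS and 0.739% in DA, so the direction of this class depends on the scaling. The tRNA share was 51.1% in DS and 51.9% in DA. The authors' q was adjusted over the tests of all 3 comparisons together. With q recomputed within this comparison, 80 features were called, and 75 passed the authors' q at 0.01.

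Nitrogen limitation genes were lower in DA in 7 of 17 tested members and higher in 0, with 10 not passing (7 lower when adjusted over the list alone). This was more than among other protein-coding features (adjusted p = 0.000240, two-sided Fisher's exact test over 48 tests). The gene of the signalling protein GlnK, at 520527 to 520865, was at 79.2 FPKM in DS and listed at 0 in DA and MM. The glutamine synthetase gene glnA was at 31.5 FPKM in DS and 1.70 FPKM in DA, 18.5-fold apart, and its locus overlaps another feature. The glutamine transport gene glnH differed 6.30-fold and the sensor kinase gene glnL 5.24-fold. Recomputing q within this comparison left 5 lower calls, still more than among other protein-coding features (adjusted p = 0.000848, two-sided Fisher's exact test). The list median of -0.94 lay at percentile 0.030 of 10000 random lists matched on expression.

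Curli and cellulose genes were lower in DA in 3 of 8 tested members (3 when adjusted over the list alone), which missed the threshold (adjusted p = 0.0519, two-sided Fisher's exact test) but passed with q recomputed within this comparison (adjusted p = 0.00900, same test). csgA fell 21.2-fold, from 59.1 to 2.79 FPKM, and csgB and csgF fell from 35.1 and 4.40 FPKM to 0. csgA and csgB lie side by side between 1231122 and 1232074. Tryptophan and aromatic biosynthesis gave 4 lower, 1 higher and 7 not passing among 12 (4 lower and 1 higher when adjusted over the list alone). Lower calls were more frequent than among other features (adjusted p = 0.0242, two-sided Fisher's exact test). tyrA differed 6.77-fold, trpB 3.02-fold, trpC 2.68-fold and trpD 2.60-fold, and the tryptophan transporter gene mtr was 3.40-fold higher in DA. With q recomputed within this comparison, 0 of these lower calls remained in the list.

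Branched-chain biosynthesis and transport was higher in DA in 9 of 19 tested members and lower in 0, with 10 not passing (9 higher and 1 lower when adjusted over the list alone). ilvC of the same pathway went the other way, at 3.84 FPKM in DS and 1.63 FPKM in DA, without a call (q = 0.0627 in the authors' deposited table). The adjusted p was 8.01e-06 by two-sided Fisher's exact test, and the list median was 1.73. ilvB, at 3995929 to 3997617, was at 25.2 FPKM in DA and 1.47 FPKM in DS, 17.1-fold apart. ilvG, at 4108986 to 4110892, differed 9.40-fold, and ilvE, ilvD and ilvA, which follow it, differed 6.79-fold, 6.79-fold and 6.27-fold. The locus of ilvG overlaps another feature. In MM these genes were at 1.02 FPKM or lower, with ilvA the highest of them.

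Gluconeogenesis and the glyoxylate shunt gave 4 higher, 2 lower and 4 not passing among 10 (5 higher and 2 lower when adjusted over the list alone). Higher calls were more frequent than among other features (adjusted p = 0.0172, two-sided Fisher's exact test). aceK, aceB and aceA, at 4402052 to 4407213, were 3.25-fold, 2.81-fold and 2.33-fold higher in DA, and acs was 2.27-fold higher. pckA and pps, of gluconeogenesis proper, were 2.12-fold and 1.82-fold lower. With q recomputed within this comparison the list kept its 4 higher calls and 0 lower ones. Genes linked to RpoS were higher in 7 of 30 and lower in 0 (3 higher when adjusted over the list alone), with an adjusted p = 0.0139 by two-sided Fisher's exact test. msyB differed 2.97-fold, yjbJ 2.48-fold, yhbO 2.45-fold and bolA 2.13-fold. With q recomputed within this comparison, 3 of the RpoS calls passed and the excess over other features no longer passed (adjusted p = 0.439, two-sided Fisher's exact test). The RpoS list also did not pass with a minimum of 10 FPKM, under which the tryptophan list had too few members to be tested.

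Ribosomal protein features were called lower in 1 of 53 and higher in 0, with a median of -0.04. Glycolysis was called in 0 of 11 and NADH dehydrogenase I in 0 of 6. The nitric oxide stress list was called in 0 of 5, although yoaG was at 89.7 FPKM in DS and 10.7 FPKM in DA, and hcr at 8.51 and 0.0924 FPKM. Over all comparisons, 15 of 52 lists held 0 calls. 6 of these had 0 tested members, so that no call was possible, among them SPI-1 type III secretion, fimbriae and propanediol use, and flagella and ethanolamine use had at most 4 and 2 tested members. The invasion list's slrP was at 0.216 FPKM in MM, 2.14 FPKM in DS and 2.02 FPKM in DA, and flhD of the flagellar list at 12.9, 5.35 and 7.54 FPKM.

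**Figure D2:**
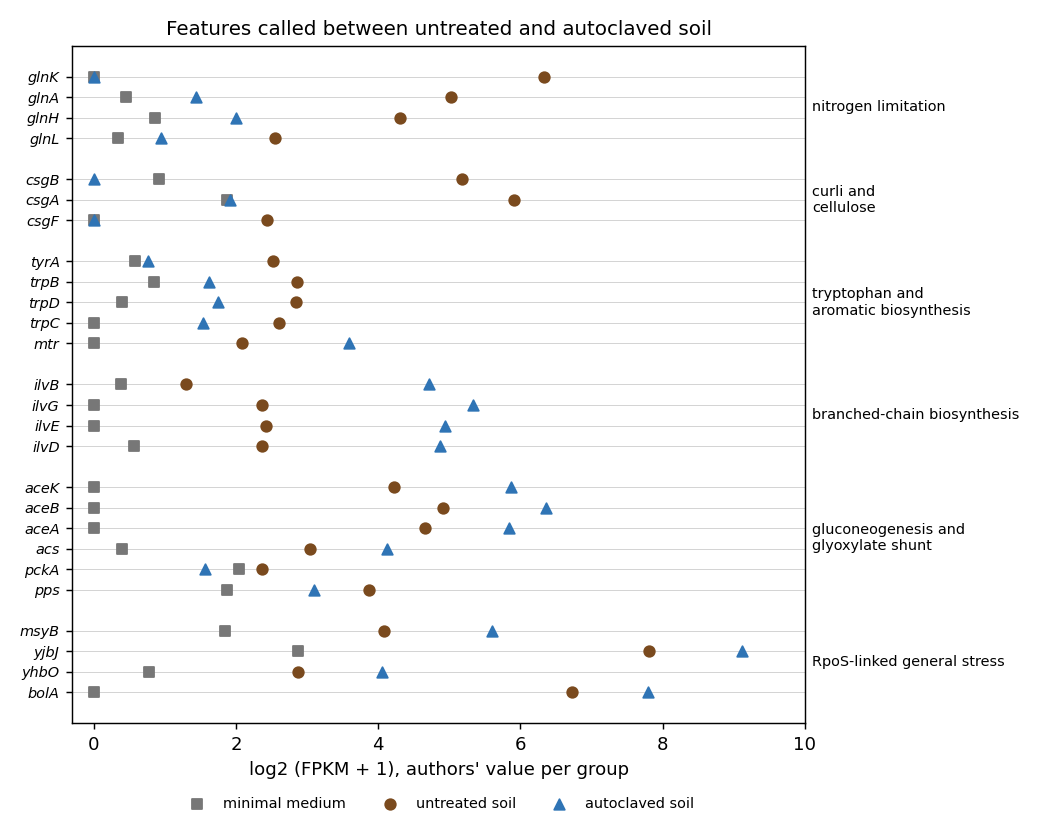
Authors' FPKM value in minimal medium, untreated soil and autoclaved soil for the features named as examples of 6 gene lists, as log2(FPKM + 1), 1 point per group without error bars. glnK lies at 79.2 FPKM in untreated soil and at 0 elsewhere, while ilvB lies at 25.2 FPKM in autoclaved soil and 1.47 FPKM in untreated soil.

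**Figure D3:**
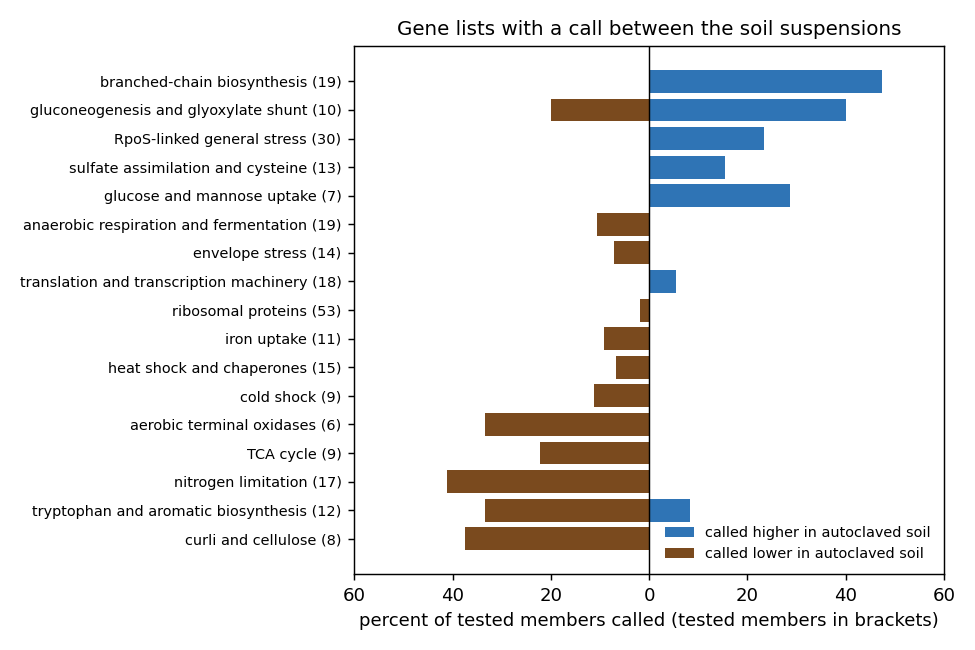
Percent of tested members called between the soil suspensions for each list with at least 5 tested members and a call, higher in autoclaved soil to the right and lower to the left. Lists are ordered by their median change. Branched-chain biosynthesis (9 of 19 higher) has the longest bar to the right and nitrogen limitation (7 of 17 lower) the longest to the left.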

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

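The tests of explanations in this part were chosen after the values they concern had been seen. 147 features differed in their response between untreated and autoclaved soil by the authors' test of that difference. Among them were 7 members of the nitrogen limitation list and 9 members of the branched-chain biosynthesis list. 5 features had at least 10 FPKM in both soil suspensions and 0 in MM but were tested in no comparison. They were STM0715, ysdB, STM4140, STM4255 and STM4478, named after their values were seen, with ysdB at 42.5 FPKM in DS and 61.6 FPKM in DA.

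Against MM, protein-coding features were higher and rRNA and tRNA features lower in both soils on the authors' scale. The share of tRNA in the summed signal was higher in the soils (51.1% in DS and 51.9% in DA, against 40.1% in MM), so the direction of tRNA turns with the scaling. Less complete rRNA removal in MM would leave tRNA level with protein-coding features, but tRNA medians lay at -2.96 in DS (95% interval -3.07 to -2.69) and -1.96 in DA relative to them, so it may account for rRNA but not for this gap. A choice of tested features as the whole cause is argued against by the summed protein-coding signal, tested or not. On the authors' scale it was 1.16 higher in DS (interval 0.50 to 1.86) and 1.37 higher in DA as a log2 ratio. The choice may account for part of the size, as tested medians were 1.98 in DS and 2.11 in DA on the log2(FPKM + 1) scale. Over protein-coding features above 0 in both media, tested or not, the median log2 ratios were 1.05 and 0.91. The absolute direction of each class stays open, as no value here fixes the scaling between media, and an effect of the medium itself was not tested. MM also differed from the soils in depth. A difference in preparation or sequencing of the MM libraries could not be told apart from the medium.

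Nitrogen limitation genes were called higher in untreated soil in 7 of 17 tested members, with 10 not called. Sequence from other soil bacteria would also raise conserved protein genes in untreated soil. The ribosomal protein list had a median of -0.041 between the soils (95% interval -0.34 to 0.18). A small added signal changes the ratio most for features near 0, and in DA glnK was at 0 and glnA at 1.70 FPKM. The ribosomal median therefore argues only against an amount large enough to move that list, and does not decide for these genes. The cells sat in dialysis tubes apart from the soil suspension, and whether soil sequence reached them was not tested. A single scaling factor would move other genes as far as the list (median -0.94). The 966 other tested protein-coding features had a median of 0.15 (interval 0.07 to 0.19). The list was flagged for holding more lower calls than these features, so this gap restates the contrast and is not a separate test. A first test, on the list median centred on protein-coding features (-1.07, interval -1.73 to -0.50), had a bound of -0.5 and did not decide. The autoclaving of the soil, the difference the design names, stays open as untested.

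Branched-chain biosynthesis genes were called higher in autoclaved soil in 9 of 19 tested members. Reads shared within 1 overlapping locus are argued against, since the 9 called members lie in 3 separate regions, one with leuD, leuC, leuA and leuB, one with ilvB and one with ilvG, ilvE, ilvD and ilvA. A single scaling factor as the whole cause would move the 964 other tested protein-coding features as far as the list (median 1.73). Their median was 0.12 (interval 0.05 to 0.18). The list was flagged for holding more higher calls than these features, so this gap restates the contrast and is not a separate test. The list itself was mixed, with 10 members not called and a wide interval of its centred median (1.60, -0.26 to 2.37), on which a first test did not decide. The autoclaving of the soil stays open as untested.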

How the results depend on the processing

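The scalings to protein-coding and rRNA features and the q recomputed within each comparison were chosen after the data were examined. No paired analysis was possible because the values were pooled over the libraries of each group. For the same reason leaving out libraries, other normalizations, a fit of only 2 groups, a simulation of shared controls and totals without rRNA were not run, nor were other splits of the samples. A minimum of 10 FPKM left 304 of the 504 calls for DS against MM and 299 of the 482 for DA against MM, and requiring values above 0 in both groups left 298 and 270, in each case by removing features. Between the soil suspensions, 75 of the 147 calls had q under 0.01, 71 had a 2-fold change with a pseudocount of 5, and 80 passed with q recomputed within the comparison. The other counts of calls stayed within 1.5 times. Higher calls for DS and DA against MM came to 61.5% and 65.1% after centring on all tested features, 57.5% and 59.1% on tested protein-coding features, and 87.5% and 90.9% with rRNA as constant. Between the soils the share was 63.9% throughout, as the shifts subtracted were small, and scaling to the summed signal was not tried. The overlap of 396 features was 283, 377 and 282 under the alternatives. Lists with more calls between the soils numbered 5, and 3 with at least 10 FPKM (nitrogen limitation, glyoxylate shunt and branched-chain biosynthesis). Recomputing q within the comparison gave 1 list for DS against MM, cold shock, against 0. Centring on all tested features reversed the heat shock median (-0.44 for DS, -0.54 for DA) and the DA changes of dppA (-0.42) and lon (-0.14), by the shift it subtracts, and 114 of 116 named changes and 20 of 22 list medians kept their direction. Depth in MM, where 54.7% of features were at 0, limits both comparisons against it.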

Other observations

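Further features, chosen after their values were seen, add to the contrast between the soils. The ammonium transporter gene amtB, next to glnK, was at 61.3 FPKM in DS, 0.328 FPKM in DA and 0.623 FPKM in MM, yet the authors' deposited table gives q = 0.123 between the soils, so it was not called. The nitrate transporter gene narK was at 6.72 FPKM in DS and 0.375 FPKM in DA, with q = 0.0625 in the authors' deposited table. The neighbours STM2786, STM2787 and STM2788 were at 16.5, 23.5 and 15.1 FPKM in DS, 2.77, 7.62 and 3.56 FPKM in DA and 0 in MM, and all were called lower in DA. nifS, next to yfhP, was at 14.6 FPKM in DA and 2.53 FPKM in DS and was called. The small RNA rprA was at 1930 FPKM in DA and 522.4 FPKM in DS and was called, while rpoS itself was at 173.8 and 183.8 FPKM, with q = 0.817 in the authors' deposited table. rpoS was at 12.8 FPKM in MM and was called higher in both soils.

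The prediction of this test was written before its result was seen. If called genes follow transcription units, neighbouring called features should share their direction. Of 17 pairs of neighbouring protein-coding features that were both called between the soils, 17 had the same direction. Permuting the directions among called features gave a median of 8 pairs and at most 15 (one-sided permutation p = 0.0001, the smallest that 10000 permutations can give). This is consistent with joint transcription of neighbours, although overlapping loci could add to it.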
